A study of Mus musculus with 12 samples.

How the data were processed

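Gene expression was measured in samples titled lymphocytes, from the pancreatic lymph node, the node that drains the pancreas. The mice were non-obese diabetic (NOD/ShiLtJ), a strain that develops autoimmune diabetes spontaneously. The 12 samples form 4 groups of 3: germ-free (GF) females, GF males, females kept under specific-pathogen-free (SPF) conditions and SPF males. GF mice carry no microbes, and SPF mice carry a microbiota without listed pathogens. The series design gives 3 mice per group, aged 9 to 10 weeks, and the replicates were taken as separate mice on that basis.

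Total RNA was purified by ultracentrifugation through caesium chloride and labelled with biotin by an Illumina amplification kit, per the labels' protocols. The arrays were Illumina mouse BeadChips with 45281 probes, read with GenomeStudio (version not stated), per the submitters' processing notes. The deposited values are a linear probe intensity per array. In all 12 columns the mean over all probes was the same, 455, so the authors had scaled each array to a common mean, and a background peak remained in every column. Which background and normalization settings the authors chose is not given in the sources used here. A separate table of unscaled scanner values was not used, because its 24 columns (12 of intensity and 12 of detection p) carry array names that no sample label holds, and columns were never assigned by order or by value. Its column names show 2 BeadChips of 6 arrays, but the chip of each sample is not known, so chip could not be entered as a block, and chip and microbiota status cannot be told apart.

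The analysis fixed before the data were examined called for background correction with negative control probes and detection p-values from the scanner table. Since that table could not be tied to samples, the scaled intensities were corrected with limma's normexp method without controls (offset 16), quantile-normalized and put on the log2 scale. Detection was replaced by a nominal p from a normal background distribution fitted per array on the log2 scale: its mode was the peak of the intensity distribution and its SD came from the values below the peak. A probe was kept where that p was under 0.05 on at least 3 of the 12 arrays, which held for 26142 probes (57.7%). Gene names came from a platform annotation table: 34885 probes had 1 symbol, 18 had several and 10378 were unnamed here. For each symbol the probe with the highest mean was tested, and unnamed probes were tested by their ID, giving 17708 tests on 12954 named genes and 4754 unnamed probes. Where the probes of a gene that is named below and passed the test differed in direction or call, this is stated beside the gene. For genes that did not pass, and for genes outside the naming rule, the other probes were not compared.

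Means of the 4 groups were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 4.59 prior degrees of freedom), and 6 comparisons were taken from that fit: males against females in SPF and in GF mice, SPF against GF in males and in females, the interaction of sex and microbiota, and SPF against GF averaged over the sexes. All p-values were two-sided and adjusted by Benjamini-Hochberg over the 17708 tests, with a threshold of 0.05. Fold changes are given as log2 differences of group means with the standard error (SE) of the fit. Where a probe was not above background on any array of 1 group, the fold is a lower bound, computed against the lowest signal among probes above background on each array of that group, and is written as at least N-fold. The number of arrays, 3 per group, limits the precision.

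A set of 33 gene lists was fixed beforehand: type I interferon-stimulated genes, interferon gamma response, cytotoxic and Th1, T cell, regulatory T cell, Th17 and follicular helper T cell, B cell, plasma cell and immunoglobulin, germinal centre, dendritic cell, macrophage and monocyte, alternative macrophage activation, neutrophil, mast cell with basophil and eosinophil, inflammatory cytokine and chemokine, NF-kB and toll-like receptor, complement, MHC class II, cell cycle, glucocorticoid response, immediate early, heat shock and unfolded protein response, ribosomal protein, mitochondrial respiration, pancreatic acinar, pancreatic islet, adipocyte, erythroid, fibroblast and matrix, endothelium, striated muscle, gut epithelium, and sex chromosome genes. The 32 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 32 lists. Camera with a correlation estimated for each list and limma's rotation test fry, which asks whether a list's genes move on balance one way, were alternatives.

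The genes named were chosen by a rule set beforehand. It took, per comparison, up to 10 rises and 10 falls of largest size among genes past the threshold whose replicates did not overlap (no such condition for the average and the interaction), and up to 4 members of smallest p of each list past its threshold. It added the sex-linked Xist, Ddx3y, Eif2s3y, Kdm5d and Uty in the sex comparisons, of which Ddx3y had no named probe, and the 10 genes of smallest p where fewer than 5 passed. It also fixed Ifng, Il1b, Tnf, Il10, Arg1, Cxcl9, Ciita and Foxp3 in every comparison, and the 3 brightest members of each list of other tissues. Genes outside the rule are marked as such.

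The alternatives were quantile normalization without background correction, median scaling in place of quantile normalization, an offset of 50, the deposited values on the log2 scale, no detection filter, detection p under 0.01 on all 12 arrays, all probes tested singly, only the groups compared, eBayes with an intensity trend and robust estimation, array weights, the replicate number as a block, an adjusted p under 0.10, leaving out each of the 12 arrays, and counts without the sex chromosome list. The fit was tested on simulated log2 values of the 17708 genes. Background correction, normalization, the detection filter and the choice of probe were not simulated. In a simulated comparison of SPF and GF males, 65.7%, 88.1% and 93.9% of genes changed by 1.5-fold, 2-fold and 3-fold were recovered. In the simulated interaction the shares were 26.9%, 67.2% and 92.4%. In each, 67, 67 and 66 genes were changed by these folds, and 10 and 5 unchanged genes were called. The noise was independent between genes and arrays, with no background gap, so these rates are not the power of the real arrays.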

Results

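The series asks how the gut microbiota shapes the difference between the sexes in autoimmune diabetes, and its 12 arrays cover GF and SPF mice of both sexes with 3 mice in each group. On the deposited scale the median probe read 116.8 to 131.1 on the 6 GF arrays and 94.8 to 110.2 on the 6 SPF arrays. The background peak lay at 100.3 to 110.5 in GF and at 76.2 to 91.1 in SPF arrays, so the 2 conditions did not overlap on either measure. Between 51.0% and 53.3% of probes were above background on GF arrays and between 52.7% and 56.1% on SPF arrays. Pearson correlations of arrays across genes were 0.983 to 0.995 within groups and 0.960 to 0.993 between groups. The first principal component held 44.6% of the variance. Although the titles say lymphocytes, Glycam1, a gene of high endothelial venules, read 11.59 to 14.49 on the log2 scale. Lyz2, of the macrophage and monocyte list, read 13.42 to 14.42. The arrays thus hold RNA of other cells too, and changes within lymphocytes cannot be told from changes in cell composition.

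Of the sex-linked genes tested, Xist, Kdm5d and Uty matched the sex label of all 12 arrays. Xist, the X-linked RNA that silences an X chromosome in female cells, read 12.00 to 12.68 on the log2 scale on the 6 female arrays and 4.80 to 5.52 on the 6 male arrays. The Y-linked Kdm5d read 7.41 to 8.05 on male and 4.68 to 5.37 on female arrays, and Uty 6.79 to 7.02 against 5.79 to 6.0. The Y-linked Eif2s3y overlapped between the sexes, with a log2 difference of 0.37 ± 0.11 SE in SPF mice (limma adjusted p = 0.307) and 0.20 ± 0.11 in GF mice (adjusted p = 0.404).

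Males and females were first compared within SPF mice, where the effect of sex is seen with a microbiota present (n = 3 and 3). Glycam1, a mucin-like ligand of L-selectin made by high endothelial venules, fell by 2.08 ± 0.23 on the log2 scale in males, a 4.22-fold difference (limma adjusted p = 0.00236). Timp4, an inhibitor of matrix metalloproteinases, was 3.69-fold higher in males (log2 1.88 ± 0.21, adjusted p = 0.00237). Among sex-linked genes, Xist was at least 92.4-fold lower in males (adjusted p = 2.46e-11), Kdm5d at least 4.12-fold higher (adjusted p = 1.63e-05) and Uty 1.95-fold higher (adjusted p = 0.000607). The matrix gene Fbln2 (log2 -0.76 ± 0.11) and the X-linked histone demethylase gene Kdm6a (-0.56 ± 0.08) were lower in males, both at adjusted p = 0.0266, with 1 of 2 and 2 of 3 of their probes past the test. In all, 8 of 17708 genes passed, 4 higher and 4 lower, of which 7 had names and 4 lay outside the sex chromosome list. These 4 include the 1 unnamed probe, which counts as outside a list of symbols whatever its gene, so it may be sex-linked. At an unadjusted p under 0.05 there were 2151 genes. The calls of Fbln2 and Kdm6a were lost without any of 9 and 8 single arrays, with adjusted p up to 0.2 and 0.182, and also without the detection filter. With only the groups compared in the fit, 3 genes passed, and Glycam1, Timp4, Uty, Fbln2 and Kdm6a lost their calls. With median scaling 36 genes passed (6 higher and 30 lower), and on the deposited scale 33 (10 and 23).

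In SPF mice 10 gene lists passed between the sexes. All 10 calls were lost with an estimated correlation (adjusted p = 0.66). The number was 1 without SPF_female 3, 3 without SPF_male 2, 4 without SPF_female 1, 6 without SPF_male 1 and 16 without SPF_female 2. Fibroblast and matrix genes were lower in males in 20 of 27 cases by sign, with a median log2 difference of -0.17 (camera adjusted p = 0.000304). Of its members 0 passed over all genes and 7 were lower when adjusted over the list alone, with the smallest p for Col6a1 (-0.49 ± 0.10) and Col4a1 (-0.50 ± 0.11). Endothelial genes had a median of -0.21 (adjusted p = 0.000304), with 1 of 21 past the test, Glycam1, and 4 when adjusted over the list alone. Cd34 (-0.51 ± 0.10) and the venule addressin gene Madcam1 (-0.58 ± 0.16) did not pass over all genes. T cell genes were also lower as a list (median -0.18, adjusted p = 0.00896), with 0 of 19 members past the test over all genes and 1 when adjusted over the list alone. The lists that were higher in males were cell cycle (median 0.12, adjusted p = 0.0033), mitochondrial respiration (0.11, 0.0114), inflammatory cytokine (0.24, 0.0117), pancreatic acinar (0.51, 0.012), macrophage and monocyte (0.19, 0.0184), MHC class II (0.17, 0.0184) and cytotoxic and Th1 genes (0.22, 0.0205), in this order. Each had 0 members past the test (limma), over all genes or over the list alone. Several lists stood apart on SPF_female 2, SPF_male 1 and SPF_male 2 and not by sex. Relative to the GF mean, inflammatory cytokine genes lay between 0.97 and 1.0 on these arrays and at 0.23, 0.14 and 0.25 on SPF_female 1, SPF_female 3 and SPF_male 3. Cytotoxic genes lay at 0.53, 0.51 and 0.64 against -0.02, -0.09 and 0.04, and T cell genes at -0.01, -0.17 and -0.15 against 0.20 on each of the other 3. Endothelial genes lay at -0.46 on SPF_female 2, below -0.39 on SPF_male 1 and -0.28 on SPF_male 3, with -0.56 on SPF_male 2. On SPF_female 1 and SPF_female 3 they lay within the GF range of -0.12 to 0.14. The cell cycle call was lost with median scaling, and the cytotoxic and acinar calls with strict detection (p under 0.01 on all 12 arrays). On the deposited scale the macrophage, MHC class II, cell cycle and respiration calls were lost (adjusted p up to 0.252), and with only the groups compared the cytotoxic call. By fry 0 of the 10 lists passed. When single arrays were left out, 9 of the 10 lists lost their call at least once, in each case without at least 1 of SPF_female 1, SPF_female 3, SPF_male 1, SPF_male 2 and SPF_male 3; the fibroblast list kept it without any 1 array. The acinar list rested on SPF_male 3 (adjusted p = 0.959 without it), the single array on which the list was high, with Amy2a5 at 11.22 against 8.01 to 9.12 on the other arrays. Its member Klk1 went another way, at 6.47 on SPF_male 3 and at 7.20, 7.08 and 7.51 on SPF_female 2, SPF_male 1 and SPF_male 2, against 6.37 to 6.71 on GF arrays.

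In GF mice the same sex comparison was made in the absence of microbes (n = 3 and 3). Glycam1 fell by 2.47 ± 0.23 on the log2 scale in males, a 5.55-fold difference (limma adjusted p = 0.000334). Xist was at least 119.5-fold lower (adjusted p = 1.61e-11), Kdm5d at least 4.87-fold higher (adjusted p = 1.33e-06) and Uty 2.10-fold higher (adjusted p = 0.000192). Lower in males were also Fut7, whose enzyme builds selectin ligands (log2 -0.75 ± 0.12, adjusted p = 0.0338), Fbln2 (-0.75 ± 0.11, 0.0311) and Ch25h, which makes 25-hydroxycholesterol (-0.75 ± 0.13, 0.0496). Dnajc15 (-0.69), Susd2 (-0.68), the X-linked Ubl4a (-0.67), Galnt9 (-0.59) and Micall2 (-0.54, past the test with 1 of its 3 probes) were lower as well, and Bpifb1 was higher (0.58 ± 0.10, adjusted p = 0.0496). Of 2 Fbln2 probes 1 passed when all probes were tested singly, and of 2 Bpifb1 probes 0 (limma). In all 21 of 17708 genes passed, 5 higher and 16 lower, 14 of them named and 17 outside the sex chromosome list. These 17 include the X-linked Ubl4a and 7 unnamed probes, whose genes are not known here and may be sex-linked. At an unadjusted p under 0.05 there were 2713 genes. Of the 13 genes named so far in GF mice, Xist, Kdm5d, Uty and Glycam1 kept their calls without every single array in turn. The calls of the other 9 were each lost without at least 8 of the 12 arrays, with adjusted p up to 0.223, and the count fell to between 5 and 9 without any 1 array other than SPF_female 2, SPF_male 1 and SPF_male 3, where it was 17, 20 and 29. These 9 were also lost without the detection filter, and all but Dnajc15 on the deposited scale. With median scaling Bpifb1, Ch25h, Susd2, Galnt9 and Micall2 lost their calls, and with only the groups compared all 9 but Fut7 and Dnajc15. The SPF differences in Kdm6a and Timp4 had the same direction here. Kdm6a read 10.91 to 11.04 in GF males and 11.42 to 11.54 in GF females, and it passed, outside the largest falls. Timp4 read 7.61 to 8.15 against 6.66 to 7.13 and did not pass.

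Genes of mitochondrial respiration were lower in GF males than in GF females as a list (median log2 -0.25, negative in 28 of 34 genes, camera adjusted p = 1.74e-07). The 3 lists called in GF mice all had adjusted p = 0.914 with an estimated correlation. None passed over all genes (limma, 0 of 34; by fry the list had adjusted p = 0.139), and 14 were lower when adjusted over the list alone, among them Atp5h (-0.71 ± 0.14), Sdhb (-0.55 ± 0.12) and Ndufa7 (-0.95 ± 0.23). Ribosomal protein genes were lower too (median -0.15, adjusted p = 0.00357), with 0 of 21 members past the test over all genes and 4 when adjusted over the list alone, such as Rpl32 (-0.62 ± 0.15). Type I interferon-stimulated genes were higher in males (median 0.35, positive in 21 of 24, adjusted p = 0.0101), with 0 members past the test over all genes and 1 when adjusted over the list alone; Mx1 had 0.70 ± 0.15. The ribosomal call was lost without GF_male 3 (adjusted p = 0.092), and the interferon call without GF_female 2, GF_female 3 or GF_male 3 (up to 0.254). The interferon call was also lost on the deposited scale (0.0502), and by fry 0 of the 3 lists passed. GF_male 3 was lowest in both falling lists: respiration genes lay at -0.29 there against -0.08 and -0.05 on the other GF males, and ribosomal genes at -0.26 against -0.06 and -0.02. The respiration call held without it.

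The interaction asks whether the sex difference itself differed between SPF and GF mice. No gene passed (limma, 0 of 17708; smallest adjusted p = 0.151), against 2308 at an unadjusted p under 0.05 and 1 with trend and robust estimation. The smallest p-values belonged to Dnajc15, with a male-to-female difference 1.03 ± 0.15 higher on the log2 scale in SPF than in GF mice, Cmpk1 (0.77 ± 0.12) and Tspan4 (0.73 ± 0.12), all at adjusted p = 0.151. They were followed by BC028528 (0.84), Trnp1 (1.22), Ptpre (1.28), H2bc7 (0.99), Ubl4a (0.81), 1110038B12Rik (0.74) and Pmm1 (0.83), with adjusted p of 0.17 to 0.221. For Glycam1 the interaction was 0.39 ± 0.32 (adjusted p = 0.632) and for Timp4 0.95 ± 0.30 (adjusted p = 0.261). The immune genes fixed beforehand did not pass either: Cxcl9 had 1.09 ± 1.20 (adjusted p = 0.729), Il1b 0.76 ± 0.69 (0.673), Ifng 0.72 ± 0.98 (0.79), Il10 0.29 ± 0.30 (0.716), Tnf 0.18 ± 0.21 (0.754), Ciita 0.06 ± 0.17 (0.91), Arg1 -0.02 ± 0.19 (0.982) and Foxp3 -0.04 ± 0.13 (0.921). The Il10 value is nominal, since its probe was not above background on any GF array. The count was 1 without GF_male 2 and 1 without SPF_male 1.

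As lists, 3 gene groups passed the test of the interaction by camera. All 3 calls were lost with an estimated correlation (adjusted p = 0.894) and by fry (adjusted p = 0.248, 0.612 and 0.612, in the order given here). The number was 11 without SPF_female 2, 9 without SPF_male 3 and 2 to 4 without any other array. Mitochondrial respiration had a median interaction of 0.41 on the log2 scale, positive in 31 of 34 genes (camera adjusted p = 1.42e-09), with 0 genes past the test over all genes and 8 higher and 1 lower when adjusted over the list alone. Examples were Sdhb (0.71 ± 0.18), Ndufc1 (0.75 ± 0.19), Ndufs3 (0.47 ± 0.12) and Atp5h (0.77 ± 0.20), each at adjusted p = 0.244. Ribosomal protein genes had a median of 0.24 (16 of 21 positive, adjusted p = 0.00104), with 0 and 3 members higher by the same counts, and cell cycle genes 0.12 (19 of 21 positive, adjusted p = 0.0131), with 0 and 0. The cell cycle call was lost with median scaling, on the deposited scale (0.295) and without GF_male 1, SPF_female 3 or SPF_male 2, the last 3 with adjusted p up to 0.15.

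**Figure D1:**
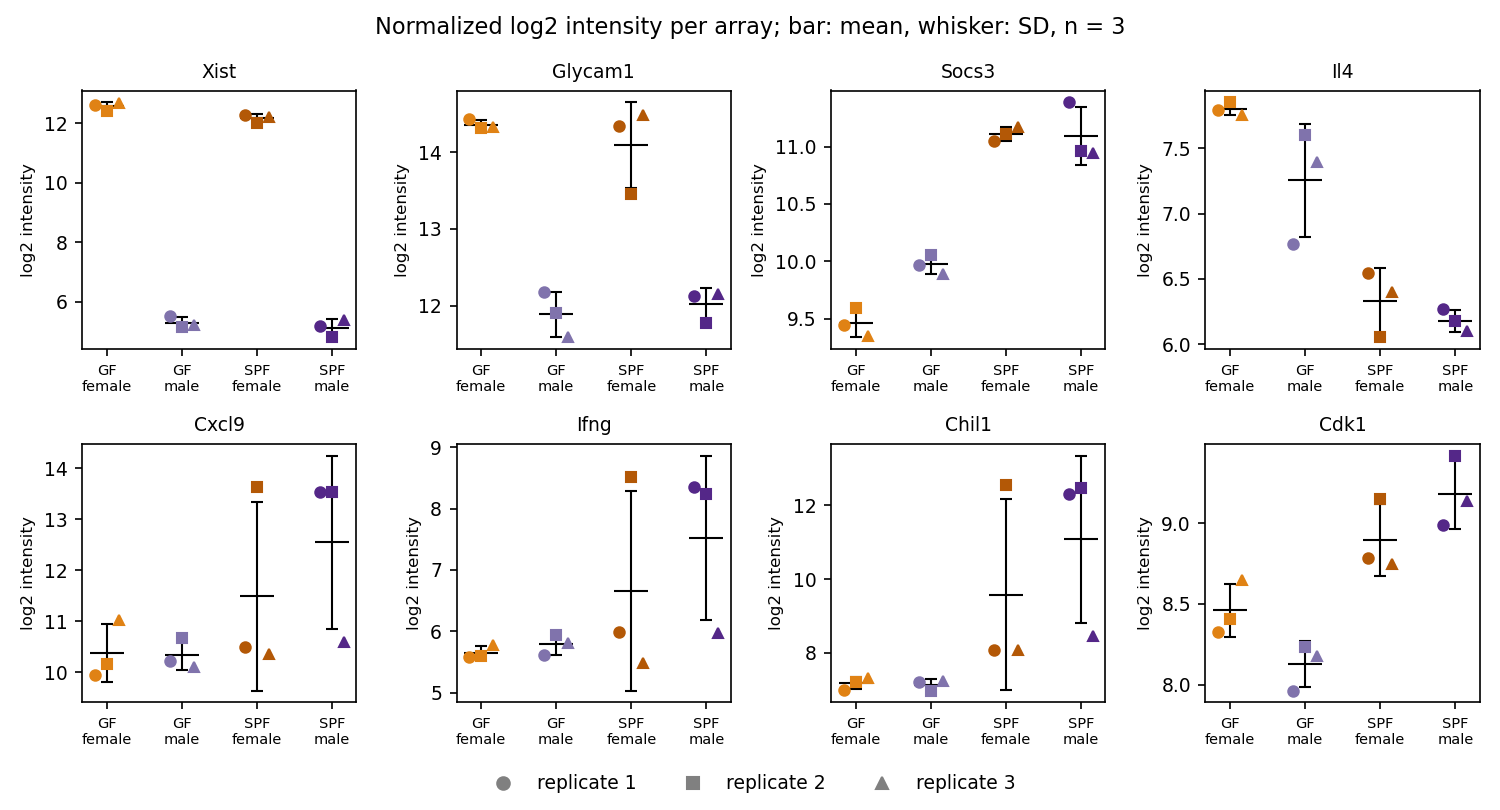
Normalized log2 intensity of 8 genes on each of the 12 arrays, by group, with the mean (bar) and SD (whisker) of 3 arrays. Xist and Glycam1 separate the sexes, Socs3 and Il4 separate SPF from GF arrays, and Cxcl9, Ifng and Chil1 are high on SPF_female 2, SPF_male 1 and SPF_male 2, where Cxcl9 reads 13.63, 13.53 and 13.53.

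SPF and GF mice were then compared within males (n = 3 and 3). The monocyte chemoattractant gene Ccl12 was 5.26-fold higher (log2 2.40 ± 0.32, limma adjusted p = 0.00161), Sirpb1a 3.89-fold (1.96 ± 0.35, 0.00443) and the matrix gene Mgp 3.86-fold (1.95 ± 0.22, 0.00104). The chitinase-like gene Chil1 was 15.4-fold higher (3.94 ± 1.13, 0.0318), the formyl peptide receptor gene Fpr2 10.5-fold (3.39 ± 1.09, 0.0487), Ccl8 9.32-fold (3.22 ± 0.79, 0.0172), Slpi 6.41-fold, Fcgr4 5.81-fold, Ubd 3.92-fold and the lectin gene Clec4e at least 3.52-fold. The largest falls were in Msh5 (-1.73 ± 0.16, adjusted p = 0.00104; 1 of its 3 probes fell), the IL-25 receptor gene Il17rb (-1.70 ± 0.20, 0.00104), the heat shock gene Hsph1 (-1.32 ± 0.16, 0.00117), Pla2g4f (-1.09), Erich5 (-1.08) and the cytokine gene Il4 (-1.07 ± 0.18, 0.00368). Tenm4 (-1.04), Pbld2 (-1.03), Arhgap22 (-1.03) and Ddx17 (-1.02, adjusted p = 0.0494) fell as well. Of the probes of Clec4e, Tenm4 and Ddx17, 1 of 2, 2 of 3 and 1 of 3 passed. Of the fixed genes, Il1b was 3.30-fold higher (1.72 ± 0.49, 0.0308) and Il10 at least 1.37-fold (0.0262). Ifng had 1.73 ± 0.69 (0.102), Cxcl9 2.21 ± 0.85 (0.0888), Ciita -0.32 ± 0.12 (0.0777), Tnf 0.32 ± 0.15 (0.163), Arg1 -0.07 ± 0.14 (0.766) and Foxp3 -0.03 ± 0.09 (0.843).

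In all, 3167 of 17708 genes differed between SPF and GF males, 1325 higher and 1842 lower in SPF, of which 146 rose and 17 fell by at least 2-fold. The split depended on the scaling: with median scaling 1552 were higher and 883 lower, and on the deposited scale, where the median of all genes lay at -0.19, 1186 were higher and 6838 lower. The count was 1021 without SPF_male 2, 1428 without GF_male 3 and 1697 without GF_male 1. Without any 1 of the 3 GF male arrays, SPF_male 1 or SPF_male 2, the calls of Chil1, Slpi, Fcgr4 and Il1b were lost (adjusted p up to 0.132, 0.133, 0.154 and 0.128), and so was that of Ccl8 without 4 of these 5 (GF_male 2 excepted; up to 0.0826). Without SPF_male 3 the log2 rises were larger: Chil1 5.25, Fpr2 4.80, Ccl8 4.06, Slpi 3.49 and Fcgr4 3.43. Without SPF_male 2 those of Chil1, Fpr2 and Ccl8 were 3.24, 2.63 and 2.60. Fpr2, Clec4e and Ddx17 lost their calls without any of 10, 9 and 10 single arrays (up to 0.189, 0.196 and 0.193), Ubd without SPF_male 2 (0.0594), and Il10 without GF_male 1, GF_male 3, SPF_male 1 or SPF_male 2 (up to 0.106). With trend and robust estimation Chil1, Fpr2, Ccl8, Slpi, Fcgr4, Clec4e, Ddx17 and Il1b lost their calls. Without the detection filter Chil1, Fpr2, Fcgr4, Clec4e and Ddx17 did, and on the deposited scale Clec4e and Il10. Clec4e and Ddx17 also lost theirs with median scaling, and these 2 and Fpr2 with only the groups compared.

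Cell cycle genes rose together in SPF males: 14 of 21 were higher and 0 lower, 16 when adjusted over the list alone (median log2 0.41, camera adjusted p = 7.27e-12). The list had adjusted p = 0.283 with an estimated correlation. Birc5 (1.11 ± 0.16), Cdk1 (1.06 ± 0.14) and Rrm2 (0.99 ± 0.15) led them. In mitochondrial respiration 10 of 34 genes rose and 0 fell, 15 and 1 over the list alone (median 0.41, adjusted p = 5.76e-08), with Ndufa2 at 0.83 ± 0.16, Ndufs3 at 0.53 ± 0.09 and Sdhb at 0.61 ± 0.12, the last with 2 of its 3 probes. The mitochondrial respiration list had adjusted p = 0.292 with an estimated correlation. Inflammatory cytokine and chemokine genes rose in 7 of 16 cases, 9 over the list alone (median 0.68, adjusted p = 0.000191), such as Cxcl1 (1.30 ± 0.29) and Il1rn (1.35 ± 0.36, 1 of 2 probes). The inflammatory cytokine list had adjusted p = 0.465 with an estimated correlation. It lay between 0.99 and 1.0 above the GF mean on SPF_male 1 and SPF_male 2 and at 0.25 on SPF_male 3. Of macrophage and monocyte genes 11 of 22 rose and 1 fell, 13 and 2 over the list alone (median 0.49, adjusted p = 0.000527), with Cd14 at 1.76 ± 0.23 and Aif1 at 1.01 ± 0.18, the latter with 1 of its 3 probes. The macrophage and monocyte list had adjusted p = 0.292 with an estimated correlation. Plasma cell genes rose in 4 of 9 cases by both counts (median 0.59, adjusted p = 0.000287): Tnfrsf17, the plasma cell receptor BCMA (1.52 ± 0.30), Mzb1 (1.48 ± 0.33), Fkbp11 (1.24 ± 0.34) and Derl3 (0.97 ± 0.25). The plasma cell list had adjusted p = 0.404 with an estimated correlation. These 5 lists kept their calls without any 1 array, while the genes Mzb1, Fkbp11, Derl3 and Il1rn each lost theirs without SPF_male 2 (adjusted p up to 0.0522, 0.107, 0.0767 and 0.0989 over all arrays). Fkbp11, Derl3 and Il1rn also lost theirs without GF_male 1, Fkbp11 and Il1rn without GF_male 3, Derl3 without GF_male 2, Il1rn without SPF_male 1, and Cxcl1 without GF_male 3 (0.0502).

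B cell genes fell in SPF males in 8 of 19 cases by both counts (median -0.21, camera adjusted p = 0.00343), among them Fcer2a (-0.78 ± 0.16), Fcmr (-0.76 ± 0.13), Cd37 (-0.43 ± 0.08) and Spib (-0.43 ± 0.09, 1 of 2 probes). The B cell list had adjusted p = 0.465 with an estimated correlation. Endothelial genes fell in 4 of 21 cases, 8 over the list alone (median -0.30, adjusted p = 0.00273): Robo4 (-0.74 ± 0.17, 1 of 2 probes), Eng (-0.58 ± 0.09), Esam (-0.48 ± 0.14) and Cdh5 (-0.47 ± 0.14, 1 of 2 probes). The endothelial list had adjusted p = 0.622 with an estimated correlation. Of the list of alternative macrophage activation 5 of 19 rose, 6 over the list alone (median 0.40, adjusted p = 0.00343), including Ccl8, Clec7a (1.21 ± 0.30) and Mgl2 (0.69 ± 0.13), each of these last with 1 of 2 probes. The alternative activation list had adjusted p = 0.283 with an estimated correlation. Relative to the GF mean it lay at 0.47 and 0.68 on SPF_male 1 and SPF_male 2 and at 0.20 on SPF_male 3. Glucocorticoid-induced genes fell in 3 of 16 cases, 4 over the list alone (median -0.29, adjusted p = 0.0285), with Per1 at -0.76 ± 0.13, Tsc22d3 at -0.56 ± 0.14 (1 of 3 probes past the test) and Ddit4 at -0.51 ± 0.15. The glucocorticoid list had adjusted p = 0.465 with an estimated correlation. Germinal centre genes rose in 2 of 9 cases, 4 over the list alone (median 0.14, adjusted p = 0.0285), Aurkb, a kinase of dividing cells (0.87 ± 0.12), and S1pr2 (0.48 ± 0.13). The germinal centre list had adjusted p = 0.283 with an estimated correlation.

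The remaining lists past the test in males rested on few members. Neutrophil genes were higher with Chil1 alone past the test, 1 of 14 and 0 over the list alone (median 0.57, camera adjusted p = 0.0435), and interferon gamma response genes with Psmb8 (0.47 ± 0.10) and Psmb9 (0.52 ± 0.16), 2 of 23 and 1 over the list alone (median 0.47, adjusted p = 0.0461). The neutrophil and interferon gamma response lists had adjusted p = 0.624 and adjusted p = 0.716 with an estimated correlation. Relative to the GF mean, the neutrophil list lay at 0.77, 1.28 and 0.15 on SPF_male 1, SPF_male 2 and SPF_male 3, and the interferon gamma list at 0.80, 0.80 and -0.11. Ribosomal protein genes (0 of 21, median 0.16, adjusted p = 0.0471) and pancreatic acinar genes (0 of 13, median 0.45, adjusted p = 0.0285) had no member past the test by limma, over all genes or over the list alone. The ribosomal protein and pancreatic acinar lists had adjusted p = 0.629 and adjusted p = 0.624 with an estimated correlation. With median scaling the neutrophil, glucocorticoid and acinar calls were lost, and with strict detection the alternative activation, glucocorticoid, ribosomal and acinar calls. On the deposited scale the B cell, glucocorticoid and endothelial calls were lost (adjusted p = 0.268, 0.49 and 0.15). Without the detection filter the interferon gamma, germinal centre and ribosomal calls were lost (up to 0.0749), and the neutrophil call with quantile normalization alone (0.0605). The ribosomal call was also lost with all probes, with only the groups compared and with array weights. By fry 8 of the 14 lists passed, and the inflammatory cytokine, endothelial, neutrophil, interferon gamma, ribosomal and acinar lists did not. The acinar call was also lost without SPF_male 3 (adjusted p = 0.715) or GF_male 2, and the glucocorticoid call without SPF_male 2 (0.0589). The germinal centre call was lost without GF_male 2 or SPF_male 1 (up to 0.0589), and the neutrophil, ribosomal and interferon gamma calls without any of 5, 6 and 7 single arrays (up to 0.19, 0.358 and 0.325). Of the genes named in these lists, Robo4 lost its call without SPF_male 2 (0.0649), Clec7a without GF_male 1 or SPF_male 2 (up to 0.0824), Tsc22d3 without GF_male 3, SPF_male 1 or SPF_male 2 (up to 0.0721), and S1pr2, Esam, Ddit4, Cdh5 and Psmb9 without any of 4, 5, 5, 6 and 6 single arrays (up to 0.104, 0.125, 0.135, 0.145 and 0.164). With median scaling Tsc22d3, Ddit4, Esam and Cdh5 lost their calls, and without the detection filter Ddit4, Esam, Cdh5, S1pr2 and Psmb9. Fkbp11 and Il1rn lost theirs with trend and robust estimation.

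In females, SPF and GF mice were compared in the same way (n = 3 and 3). Socs3, an inhibitor of cytokine signalling, was 3.13-fold higher in SPF females (log2 1.65 ± 0.12, limma adjusted p = 9.59e-05), and Ffar2, a receptor of short-chain fatty acids, 2.31-fold (1.21 ± 0.21, 0.00915). Zbtb32 (1.32 ± 0.19, 0.00336), Ccl12 (1.52 ± 0.32, 0.0187), Tnfrsf17 (1.20 ± 0.30, 0.0336), the cold-inducible Cirbp (1.19 ± 0.16, 0.00279), Gm5643 (1.13), Rbbp7 (1.10, with 3 of its 4 probes), the chemokine gene Cxcl1 (1.04 ± 0.29, 0.0486) and Hnrnph2 (1.03) also rose. The chemokine gene Ccl17 was 3.52-fold lower (-1.82 ± 0.28, 0.00533), Hspb1 2.93-fold (-1.55 ± 0.15, 0.000593), Il17rb 2.90-fold (-1.53 ± 0.20, 0.00254) and Il4 2.77-fold (-1.47 ± 0.18, 0.00162). Further falls were in Msh5 (-1.58 ± 0.16, with 2 of its 3 probes), Ptpre (-1.27, with 1 of its 4 probes), Apol7c (-1.14), 1700030K09Rik (-1.11), H2bc4 (-1.11) and Adamtsl4 (-1.07). None of the fixed immune genes passed in females (limma, 0 of 8 at adjusted p under 0.05): Ciita had -0.38 ± 0.12 (0.0685), Il10 0.50 ± 0.21 (0.167), Il1b 0.97 ± 0.49 (0.235), Ifng 1.01 ± 0.69 (0.383), Cxcl9 1.12 ± 0.85 (0.432), Tnf 0.14 ± 0.15 (0.598), Arg1 -0.05 ± 0.14 (0.844) and Foxp3 0.01 ± 0.09 (0.965). Il10 was not above background on any GF array, so its log2 difference is nominal.

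In all, 1251 of 17708 genes differed between SPF and GF females, 563 higher and 688 lower in SPF, of which 35 rose and 19 fell by at least 2-fold. With median scaling 2581 were higher and 258 lower, and on the deposited scale, with a median of all genes of -0.15, 1567 were higher and 6251 lower. The count was 349 without SPF_female 1, 458 without GF_female 3, 483 without SPF_female 3, 545 without GF_female 2 and 696 without SPF_female 2. Without GF_female 2 the call of Ccl12 was lost (adjusted p = 0.0609), and that of Tnfrsf17 without GF_female 2 or any 1 SPF female array (up to 0.0907). The call of Cxcl1 was lost without any of 9 arrays (up to 0.125). With only the groups compared, Ccl12, Tnfrsf17, Rbbp7 and Cxcl1 lost their calls, and without the detection filter Tnfrsf17 and Cxcl1.

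Cell cycle genes rose in SPF females in 7 of 21 cases, 11 over the list alone (median 0.32, all 21 positive, camera adjusted p = 8.83e-08), for example Rrm2 (0.73 ± 0.15), Plk1 (0.61 ± 0.14) and Cdc20 (0.58 ± 0.12, 2 of 4 probes). The cell cycle list had adjusted p = 0.432 with an estimated correlation. Heat shock and unfolded protein response genes fell in 5 of 22 cases, 8 over the list alone (median -0.14, adjusted p = 0.0165), led by Hspb1, Hsph1 (-0.94 ± 0.16) and Hyou1 (-0.54 ± 0.13). The heat shock list had adjusted p = 0.432 with an estimated correlation. Inflammatory cytokine genes rose in 2 of 16 cases, 3 over the list alone (median 0.46, adjusted p = 0.00515), Cxcl1 and Il1a (0.71 ± 0.19). The inflammatory cytokine list had adjusted p = 0.563 with an estimated correlation. Macrophage and monocyte genes rose in 2 of 22 cases, with 7 higher and 1 lower over the list alone (median 0.21, adjusted p = 0.0267), Lyz2 (0.47 ± 0.09) and Mpeg1 (0.66 ± 0.17), each with 1 of 2 probes. The macrophage and monocyte list had adjusted p = 0.522 with an estimated correlation. Plasma cell genes rose with Tnfrsf17 alone, 1 of 9 and 3 over the list alone (median 0.34, adjusted p = 0.0159), and the neutrophil list passed with 0 of 14 members called by limma and 0 over the list alone (median 0.68, adjusted p = 0.0267). The plasma cell and neutrophil lists had adjusted p = 0.558 and adjusted p = 0.584 with an estimated correlation. Relative to the GF mean, the neutrophil list lay at 1.96 on SPF_female 2 against 0.09 and 0.24 on the other SPF females, the plasma cell list at 0.88 against 0.17 and 0.32, and the inflammatory cytokine list at 0.97 against 0.23 and 0.14. Endothelial genes fell in 2 of 21 cases by both counts, Tie1 (-0.85 ± 0.14) and Eng (-0.45 ± 0.09) (median -0.24, adjusted p = 0.032). The endothelial list had adjusted p = 0.618 with an estimated correlation. B cell genes fell in 3 of 19 cases, 4 over the list alone, Cr2 (-0.68 ± 0.11), Fcer2a (-0.67 ± 0.16, 2 of 3 probes) and Cd79b (-0.39 ± 0.09, 1 of 2 probes) (median -0.14, adjusted p = 0.0321), but relative to the median of all genes this list's median was -0.11 here and turned to 0.08 on the deposited scale. The B cell list had adjusted p = 0.584 with an estimated correlation.

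With median scaling 1 of the 8 list calls in females remained, cell cycle, and with strict detection 2, cell cycle and inflammatory cytokine. On the deposited scale the neutrophil, heat shock, endothelial and B cell calls were lost (adjusted p = 0.106, 0.722, 0.886 and 0.756). By fry the cell cycle and heat shock lists passed. The neutrophil and endothelial calls were also lost with array weights. Only the cell cycle list kept its call in females without any 1 array. The inflammatory, plasma cell, macrophage, neutrophil, endothelial and B cell calls were lost without SPF_female 2 (adjusted p up to 0.0669, 0.153, 0.111, 0.451, 0.627 and 0.134 over all arrays). The macrophage, neutrophil and B cell calls were also lost without GF_female 2, the neutrophil, endothelial and B cell calls without GF_female 1, the B cell call without SPF_female 3, and the heat shock call without GF_female 1 (0.0954). Of the genes named, Cdc20 lost its call without GF_female 3 (0.0609), Eng without SPF_female 1 (0.0597), and Plk1, Cd79b, Fcer2a, Hyou1, Mpeg1 and Il1a without any of 3, 3, 4, 4, 7 and 9 arrays (up to 0.0844, 0.071, 0.094, 0.105, 0.128 and 0.144). These genes and Rrm2 also lost their calls with only the groups compared. With median scaling Eng, Cd79b, Fcer2a and Hyou1 lost theirs, on the deposited scale Il1a, and without the detection filter Plk1, Cd79b, Fcer2a, Hyou1, Mpeg1 and Il1a. Endothelial genes lay at -0.46 on SPF_female 2 alone and within the range of the 6 GF arrays on the other 2 SPF females.

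The male and female comparisons use group means of separate arrays. Their log2 changes correlated at Pearson's r = 0.62 and Spearman's rho = 0.50 across 17708 genes, which are not independent replicates. Of the genes called in both, 280 were higher in both, against 42.1 for independent lists, 367 were lower in both, against 71.6, and 3 went opposite ways. The calls are not independent, since both used the same fit with a shared residual variance per gene. Without GF_female 2, for example, the male count was 2836. Both comparisons also share the background difference between GF and SPF arrays, so the overlap is not separate support. The male and female groups compared here hold 3 arrays each, so an exchange of labels cannot give a p below 0.10. For sex, 3 genes were higher and 4 lower in males in both SPF and GF mice.

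**Figure D2:**
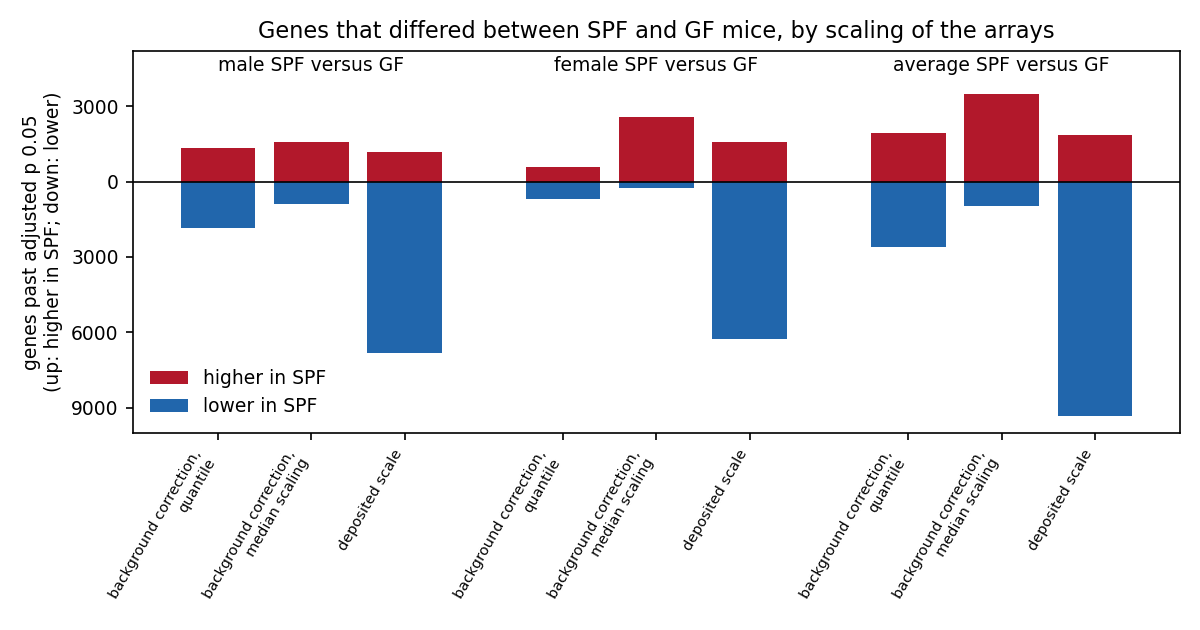
Number of genes past an adjusted p of 0.05 that were higher (up) or lower (down) in SPF than in GF mice, in males, in females and averaged over the sexes, for 3 ways of scaling the arrays. Averaged over the sexes 1943 genes were higher and 2622 lower with quantile normalization, and the deposited scale gave 1852 and 9344.

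Averaged over the sexes, 6 SPF mice were compared with 6 GF mice. Ccl12 was 3.88-fold higher in SPF mice (log2 1.96 ± 0.22, limma adjusted p = 0.000211), Chil1 9.01-fold (3.17 ± 0.80, 0.0125), Ccl8 5.42-fold (2.44 ± 0.56, 0.0081), Hcar2 at least 2.38-fold (0.012) and Ccl7 2.98-fold (1.57 ± 0.43, 0.0183). Fpr2 (2.77 ± 0.77, 0.02), Slpi (1.92 ± 0.54, 0.0205) and Fcgr4 (1.89 ± 0.54, 0.022) rose too, as did Acod1, whose enzyme makes itaconate in activated macrophages (at least 3.29-fold, 0.0314), and Clec4e (at least 2.48-fold, 0.0292). The largest falls were in Msh5 (-1.66 ± 0.11, adjusted p = 1.19e-05; 1 of its 3 probes), Il17rb (-1.62 ± 0.14, 5.66e-05), Ccl17 (-1.28 ± 0.20, 0.00115), Il4 (-1.27 ± 0.13, 0.000103), Hspb1 (-1.23 ± 0.11, 5.66e-05) and Hsph1 (-1.13 ± 0.12, 0.000113), followed by 1700030K09Rik (-1.06), Apol7c (-0.99), Reln (-0.99) and Tspoap1 (-0.95). Il1b was 2.54-fold higher (1.34 ± 0.34, 0.0138), Il10 at least 1.32-fold higher (0.00919) and the MHC class II transactivator gene Ciita 1.28-fold lower (-0.35 ± 0.08, 0.00967). Ifng had 1.37 ± 0.49 (0.0568), Cxcl9 1.66 ± 0.60 (0.0582), Tnf 0.23 ± 0.11 (0.134), Arg1 -0.06 ± 0.10 (0.679) and Foxp3 -0.01 ± 0.06 (0.913). In all 4565 of 17708 genes differed, 1943 higher and 2622 lower, of which 121 rose and 11 fell by at least 2-fold. With median scaling 3468 were higher and 988 lower, and on the deposited scale, with a median of all genes of -0.18, 1852 and 9344. Without SPF_male 2 the calls of Fpr2, Slpi and Fcgr4 were lost (adjusted p up to 0.0513, 0.0522 and 0.056), that of Fcgr4 also without SPF_male 1, and those of Acod1 and Clec4e without any of 7 arrays (up to 0.0773 and 0.0721). With trend and robust estimation Fpr2, Acod1, Slpi, Fcgr4, Clec4e and Ccl7 lost their calls, with median scaling Ciita and on the deposited scale Il10. Without SPF_female 2 the log2 rises of Chil1 and Fpr2 were 2.42 and 2.12, and without SPF_male 3 they were 3.83 and 3.48.

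Several of these rises sat on the same 3 arrays. Cxcl9, a chemokine induced by interferon gamma, read 13.63, 13.53 and 13.53 on SPF_female 2, SPF_male 1 and SPF_male 2 and 9.94 to 11.02 on the other 9. Ifng read 8.52, 8.35 and 8.24 there and 5.49 to 5.98 elsewhere, Il1b 9.39, 9.48 and 9.47 against 7.03 to 7.76, and Chil1 12.56, 12.31 and 12.48 against 6.98 to 8.46. The neutrophil list stood 1.96, 0.77 and 1.28 above the GF mean on these arrays and -0.07 to 0.24 on the other 9. Socs3 and Il4, by contrast, separated all 6 SPF from all 6 GF arrays, at 10.94 to 11.39 against 9.35 to 10.06 and at 6.05 to 6.54 against 6.77 to 7.85.

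Averaged over the sexes, cell cycle genes rose in 18 of 21 cases by both counts (median 0.38, camera adjusted p = 7.94e-12), such as Rrm2 (0.86 ± 0.11), Birc5 (0.85 ± 0.11) and Cdc20 (0.68 ± 0.09). The cell cycle list had adjusted p = 0.248 with an estimated correlation. Inflammatory cytokine genes rose in 9 of 16, 10 over the list alone (median 0.57, adjusted p = 0.000148), with Cxcl1 (1.17 ± 0.20) and Il1a (0.76 ± 0.14), and plasma cell genes in 5 of 9, 6 over the list alone (median 0.52, adjusted p = 0.000294), with Tnfrsf17 (1.36 ± 0.21) and Mzb1 (0.87 ± 0.23). The inflammatory cytokine and plasma cell lists had adjusted p = 0.426 and adjusted p = 0.368 with an estimated correlation. Of macrophage and monocyte genes 13 of 22 rose and 3 fell, 14 and 3 over the list alone (median 0.38, adjusted p = 0.00121), and of mitochondrial respiration 7 of 34 rose and 1 fell, 6 and 0 over the list alone (median 0.13, adjusted p = 0.00121). The macrophage and monocyte and mitochondrial respiration lists had adjusted p = 0.256 and adjusted p = 0.426 with an estimated correlation. In females the median of mitochondrial respiration was -0.03, with 0 genes higher and 1 lower (camera adjusted p = 0.925, limma for the genes). Endothelial genes fell in 11 of 21 by both counts (median -0.26, adjusted p = 0.00244), with Robo4 (-0.55 ± 0.12, 1 of 2 probes), Tie1 (-0.53 ± 0.10) and Eng (-0.51 ± 0.06). The endothelial list had adjusted p = 0.531 with an estimated correlation. It lay at -0.46, -0.39, -0.56 and -0.28 on SPF_female 2 and the 3 SPF males, but within the GF range of -0.12 to 0.14 on SPF_female 1 and SPF_female 3. B cell genes fell in 9 of 19 by both counts (median -0.17, adjusted p = 0.00279), with Fcer2a (-0.72 ± 0.11) and Cr2 (-0.57 ± 0.08); relative to the median of all genes this list lay at -0.13 and turned to 0.04 on the deposited scale. The B cell list had adjusted p = 0.426 with an estimated correlation.

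Further lists past the test in the average were alternative macrophage activation (6 of 19 higher, 7 over the list alone, median 0.19, camera adjusted p = 0.0107), with Retnla (0.85 ± 0.19) and Ccl6 (0.75 ± 0.20), and neutrophil genes (3 of 14 higher, 2 over the list alone, median 0.66, adjusted p = 0.0107). The alternative activation and neutrophil lists had adjusted p = 0.248 and adjusted p = 0.493 with an estimated correlation. Relative to the GF mean, the alternative activation list lay at 0.51, 0.47 and 0.68 on SPF_female 2, SPF_male 1 and SPF_male 2. It lay at 0.15, 0.22 and 0.20 on SPF_female 1, SPF_female 3 and SPF_male 3, and at -0.12 to 0.07 on GF arrays. Germinal centre genes rose in 3 of 9, with 3 higher and 1 lower over the list alone (median 0.14, adjusted p = 0.0261), including S1pr2 (0.55 ± 0.09) and Fas (0.31 ± 0.08). The germinal centre list had adjusted p = 0.248 with an estimated correlation. Glucocorticoid-induced genes fell in 6 of 16 and rose in 1, 7 and 1 over the list alone (median -0.21, adjusted p = 0.0261), led by Per1 (-0.70 ± 0.09). The glucocorticoid list had adjusted p = 0.426 with an estimated correlation. Complement genes rose in 6 of 16 and fell in 1, 6 and 2 over the list alone (median 0.14, adjusted p = 0.0366), with C1qa (0.73 ± 0.14) and C1qc (0.54 ± 0.10) higher and Cr2 lower. The complement list had adjusted p = 0.248 with an estimated correlation. Interferon gamma response genes rose in 4 of 23 and fell in 2, 6 and 3 over the list alone (median 0.36, adjusted p = 0.0208), with Psmb8 (0.53 ± 0.07) higher and Ido1 (-0.47 ± 0.11) lower, and cytotoxic and Th1 genes rose in 5 of 17 and fell in 1, 7 and 3 over the list alone (median 0.21, adjusted p = 0.0388), with Gzmk (0.61 ± 0.14) and Il18rap (0.75 ± 0.19, 1 of 2 probes). The interferon gamma response and cytotoxic lists had adjusted p = 0.694 and adjusted p = 0.625 with an estimated correlation. Both lists were raised on SPF_female 2, SPF_male 1 and SPF_male 2 only: relative to the GF mean, the interferon gamma list lay at 0.99, 0.80 and 0.80 there and at -0.03, -0.11 and -0.11 on the other 3 SPF arrays, where the cytotoxic list lay at -0.02, -0.09 and 0.04. Heat shock and unfolded protein response genes fell in 10 of 22 and rose in 1 by both counts (median -0.15, adjusted p = 0.0388); relative to the median of all genes this list lay at -0.12, and at 0.0003 on the deposited scale. The heat shock list had adjusted p = 0.256 with an estimated correlation. The interferon gamma call was lost without SPF_female 2, SPF_male 1 or SPF_male 2 (adjusted p up to 0.0817), the complement call without SPF_female 3 or SPF_male 1 (up to 0.0554), and the heat shock call without GF_female 1, SPF_female 3, SPF_male 1 or SPF_male 3 (up to 0.0922). The cytotoxic call was lost without GF_female 1, GF_female 2, GF_male 3, SPF_female 2, SPF_male 1 or SPF_male 2 (up to 0.127). With median scaling 8 of the 15 list calls remained, and the interferon gamma, cytotoxic, B cell, alternative activation, neutrophil, glucocorticoid and heat shock calls were lost. With strict detection the cytotoxic, alternative activation, complement, glucocorticoid and heat shock calls were lost. On the deposited scale the endothelial, B cell, glucocorticoid and heat shock calls were lost (adjusted p = 0.37, 0.532, 0.871 and 0.964). Relative to the median of all genes, the glucocorticoid list lay at -0.18 and moved to -0.01 on that scale, and the endothelial list went from -0.23 to -0.09. By fry 11 of the 15 lists passed, and the interferon gamma, cytotoxic, neutrophil and respiration lists did not. Gzmk, Il18rap and Ccl6 lost their calls on the deposited scale, and Mzb1 with trend and robust estimation. The cytotoxic call was also lost with quantile normalization alone (0.0508) and with array weights.

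**Figure D3:**
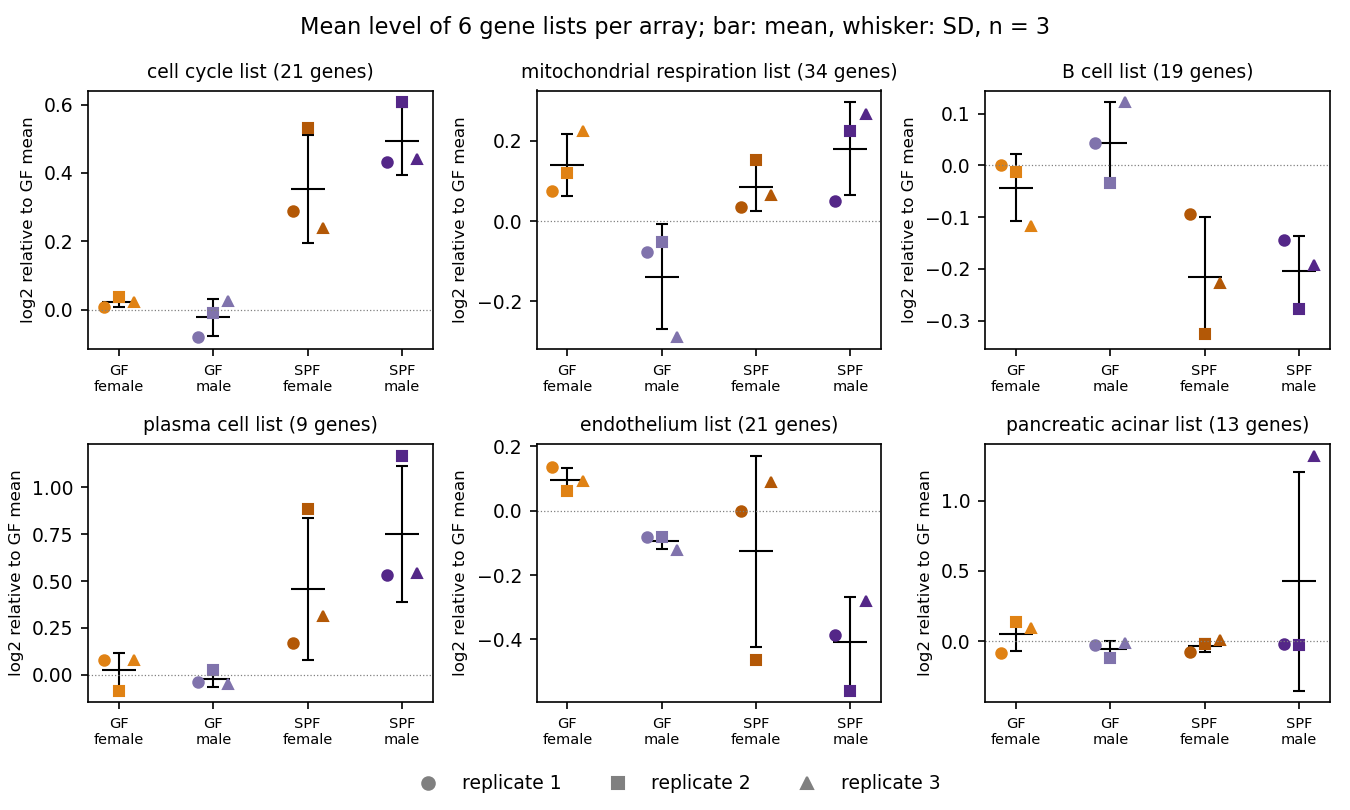
Mean level of 6 gene lists on each of the 12 arrays, as log2 relative to the GF mean, by group, with the mean (bar) and SD (whisker) of 3 arrays. Cell cycle genes are above the GF arrays on all 6 SPF arrays, and the pancreatic acinar list is high on SPF_male 3 alone, at 1.32.

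Across the 6 comparisons 53 list calls were made by camera, and with an estimated correlation 0 of them held. Of the lists tested, 11 were called in no comparison, with lowest adjusted p between 0.0645 and 0.84: regulatory T cell (0.242), Th17 and follicular helper (0.349), dendritic cell (0.122), mast cell, basophil and eosinophil (0.125), NF-kB and toll-like receptor (0.452), immediate early (0.186), adipocyte (0.12), erythroid (0.84), striated muscle (0.0645), gut epithelium (0.479) and sex chromosome genes (0.342). The islet list had 3 measured members and was not tested.

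Among the brightest members of the lists of other tissues, SPF mice averaged over the sexes had lower Tspan33 (log2 -0.48 ± 0.08, limma adjusted p = 0.00153), Des (-0.39 ± 0.08, 0.00595), Tpm2 (-0.33 ± 0.08, 0.00833) and Lgals4 (-0.41 ± 0.10, 0.0116; 2 of 3 probes) and higher Gp2 (0.26 ± 0.07, 0.0188). Whether these genes mark those tissues in a lymph node was not tested. Amy2a5 (0.36 ± 0.41), Ins2 (-0.08 ± 0.09), Hba-a1 (0.43 ± 0.36), Lpl (0.52 ± 0.25) and Tnni2 (-0.18 ± 0.09) did not pass. With median scaling Des, Tpm2 and Lgals4 lost their calls, and Gp2 on the deposited scale.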

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

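For the lists with a differing sex effect, the tests of 1 array and of probe brightness were chosen once the list call had been seen, but before their own values were. In the interaction of sex and microbiota, 3 lists passed although 0 genes did: mitochondrial respiration (camera adjusted p = 1.42e-09), ribosomal protein (adjusted p = 0.00104) and cell cycle (adjusted p = 0.0131). With an estimated correlation all 3 calls were lost (adjusted p = 0.894), and by fry as well (0.248, 0.612 and 0.612). The ribosomal and cell cycle differences were not tested further.

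For mitochondrial respiration, the list might rest on 1 array, but the highest camera adjusted p over the 12 fits without 1 array was 8.57e-08, which argues against 1 array alone. These fits cannot show what several arrays do together. Relative to the GF mean, the list lay at 0.22 on GF_female 3, the highest GF female, at -0.29 on GF_male 3, the lowest GF male, and at 0.27 on SPF_male 3, the highest SPF male. The interaction might also follow from probe brightness, but its median of 0.41 was above 100% of 10000 lists matched in intensity, whose central range was -0.168 to 0.0598. The list call did not hold with an estimated correlation (adjusted p = 0.894), so correlated movement of the members among 12 mice remains possible. When the sex labels were exchanged within each microbiota status, 100 of 100 splits had at least as many genes as the real count of 0, and the highest other had 377. Any split reaches a count of 0, so these splits cannot tell the real grouping from chance.

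For the 4565 genes that differed between SPF and GF mice, the tests of batch and of a linked interval were chosen only after the result was seen. The background and scaling of the arrays could account for part of it: 49.8% of them kept their call and direction under all 4 other scalings, 1333 higher and 939 lower. A BeadChip or batch that coincided with microbiota status is possible and cannot be told apart, since the log2 background of the lowest GF array lay 0.139 above that of the highest SPF array. A linked interval that differs between the colonies cannot be told apart either, since only the 100 named genes of smallest p were searched: 4 pairs lay within 1 Mb (median 8 and 95th percentile 15 in random draws), all with both genes lower, among them Msh5 (-1.66) and Ehmt2 (-0.50). Ehmt2 lies outside the naming rule. With microbiota labels exchanged within each sex, 1 of 100 splits reached the real 4565, namely the real one, and the highest other had 1.

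For the 3 SPF arrays with the highest Ifng and Cxcl9, the tests of carried-over pancreas and blood were chosen only after the result was seen, and the test of scaling before its own value was. Pancreas carried over with the node might raise them, but on the acinar list 3 of the 3 arrays lay within the GF range, although its member Klk1 read 7.20, 7.08 and 7.51 there against 6.37 to 6.71 on GF arrays. Blood is a further possibility. On the erythroid list 3 of 3 lay within the GF range of -0.164 to 0.234, with SPF_female 2 near its top at 0.228. That list holds red cell genes, so it cannot exclude white blood cells. Under each of 5 scalings Cxcl9 was at least 2.47 higher on the log2 scale on these 3 arrays than on any other, so the choice among these scalings did not produce the gap. All 5 start from the values as the authors had scaled them, and that step was not varied. The cause was not tested further.

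For the comparisons of 3 with 3 arrays, the splits were tests fixed before the results were seen, and 10 splits are too few for a share under 0.05. In SPF mice 2 of 10 splits reached the real count of 8 for sex, and the highest other, SPF_female 1, SPF_female 3 and SPF_male 3 against the rest, had 588. In GF mice 1 of 10 reached the real 21, and the highest other had 2. For SPF against GF mice, 1 of 10 reached the real 3167 in males, with 1 as the highest other, and 1 of 10 the real 1251 in females, with 0.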

How the results depend on the processing

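For sex in SPF mice the count of 8 became 15 with quantile normalization alone, 36 with median scaling, 33 on the deposited scale, 4 with strict detection, 13 with all probes, 3 with only the groups compared, 14 with trend and robust estimation, 18 with array weights, 13 at adjusted p under 0.10 and 4 without the sex chromosome list. In GF mice 21 became 10 on the deposited scale, 7 without the detection filter, 71 with trend and robust estimation and 135 at adjusted p under 0.10. For SPF against GF males 3167 became 8024 on the deposited scale and 1780 without the filter. In females 1251 became 2839 with median scaling, 7818 on the deposited scale, 423 without the filter, 1963 with all probes, 308 with only the groups compared and 2539 at adjusted p under 0.10. The average of 4565 became 11196 on the deposited scale, and the interaction of 0 became 1 with trend and robust estimation. There were 53 list calls, 35 with strict detection, 0 with an estimated correlation and 34 by fry, and of the 53 median scaling kept 34, the deposited scale 36, strict detection 34 and fry 21. The neutrophil list had too few members left to be tested with strict detection. On the deposited scale the B cell list in females turned upward (adjusted p = 0.756) and Chgb in the average turned to -0.22. Without 1 array at a time the counts ran from 6 to 12, 5 to 29, 1021 to 3456, 349 to 1298, 0 to 1 and 3411 to 4583 for sex in SPF, sex in GF, males, females, interaction and average, and list calls from 42 to 63. With the replicate number as a block they were 7, 14, 3413, 1403, 0 and 4772, with 54 list calls. Fbln2 and Kdm6a in SPF mice, Bpifb1, Fut7, Susd2 and Galnt9 in GF mice and the ribosomal list in males (adjusted p = 0.0502) were not called in that fit. The labels give the number alone and no pairing. Deviations of the arrays from their own group mean were therefore correlated across genes. For SPF males and females of numbers 1, 2 and 3 these deviations correlated at 0.002, 0.57 and 0.44. Number 2 pairs SPF_female 2 with SPF_male 2, which both stood apart on several lists, such as inflammatory cytokine genes. On that list neither SPF array of number 3 stood apart, and of number 1 SPF_male 1 alone did. The SPF correlations therefore cannot tell a pairing by number from that pattern. The deviations of the other same-numbered pairs correlated at -0.23 to 0.17. By the same deviations, 7 of 12 arrays correlated best with their own number in the other groups, and some such matches arise by chance. This is a hint from the data, not the design, and not every pair was over 0.1. The BeadChip block was not run, since the chip of each sample is not known. The cause of these differences was not tested.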

Other observations

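Of the 18 genes in the dendritic cell list, 5 were lower and 2 higher in SPF mice averaged over the sexes. Apart from Ccl17, these genes lie outside the naming rule, and their other probes were not compared. Fscn1 (log2 -0.95 ± 0.08, limma adjusted p = 5.31e-05), the chemokine genes Ccl17 (-1.28 ± 0.20) and Ccl22 (-0.55 ± 0.08, 0.000703), Batf3 (-0.54 ± 0.08, 0.000915) and Cd83 (-0.45 ± 0.08, 0.00242) fell, while Xcr1 (0.38 ± 0.11, 0.0301) and Ly75 (0.43 ± 0.12, 0.0206) rose. The dendritic cell list of 18 genes lay 0.18 to 0.21 below the GF mean on all 6 SPF arrays and between -0.06 and 0.07 on the GF arrays. Compared with other genes it did not pass (camera adjusted p = 0.13), and by fry, which makes no such comparison, it had adjusted p = 0.000281.

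Some genes changed by similar amounts in males and females, picked after the values were seen. Of those given, Mme, Hmgb2, Gad1 and Serpinh1 lie outside the naming rule. In males and females in turn, the log2 change was 1.22 and 1.32 for Zbtb32, 1.06 and 1.21 for Ffar2, 0.93 and 1.03 for Mme and 1.12 and 0.86 for Hmgb2. Falls of this kind were -0.96 and -1.02 for Reln, -0.88 and -0.81 for Gad1, and -0.78 and -0.83 for Serpinh1, a collagen chaperone gene.

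The acinar list was high on SPF_male 3 alone, where it stood 1.32 above the GF mean against -0.12 to 0.14 on the other 11 arrays. Cela3b read 7.58 there and 5.18 to 5.86 elsewhere. Klk1, another member, read 6.47 there, within the GF range.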
